A study of Mus musculus with 2 samples.

How the data were processed

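RNA of pancreatic lymph nodes from 16-week-old female non-obese diabetic (NOD) mice, a strain that develops autoimmune diabetes, was measured on 2 two-colour Agilent-014868 mouse arrays. Per the labels, the Cy5 channel of each array held 1 hyperglycemic mouse (blood glucose above 500 mg/dl), and the Cy3 channel of both arrays held the same pool of 2 euglycemic mice (below 200 mg/dl). Per the labels, 1 ug of total RNA per sample was amplified and labelled with the Agilent low RNA input kit. The 2 hyperglycemic mice are the replicates (n = 2). The pool is a single control sample read on both arrays, so the spread among control mice was not measured. Cy5 always held the hyperglycemic sample, so a dye effect of a single gene cannot be separated from the difference between the groups. Both arrays were on the same slide, which leaves no slide batch to test. No paired analysis was possible because the same control pool was set against each mouse.

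Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, and the spot and background columns hold scanner intensity with no normalization. The processed signals are intensity values that, per the file headers, were background-subtracted with spatial detrending, replaced by surrogates where not above background, and dye-normalized with a linear factor and LOWESS. The log ratio column holds log10 of Cy5 over Cy3 processed signals, per the file headers and the values themselves. A p-value from the error model of the scanning software for a single array is given beside it, per the file headers, and was not used. The deposited value table holds log2 ratios of Cy5 over Cy3 for 5098 probes. These log2 ratios equal the log10 ratios of the scanner files times a slope of 3.32 (r = 1.00 over probes). Of these probes 26 were controls, and the other 5072 were all well above background in both channels on both arrays, a property that 5077 probes of the array had. How the probes of the deposited value table were chosen is not stated, and its columns have medians of 0.08 and 0.03.

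Each array held 45018 spots, of which 43379 carried gene probes. The median Cy3 signal was 234 on array 1 and 81.2 on array 2, over local backgrounds of 31 and 31.5. The median Cy5 signal was 37.7 and 38.2 over a background of 35 on each array. Gene spots well above background made up 21.7% and 63.0% in Cy3, and 14.5% and 16.4% in Cy5. No spot was saturated, and 338 and 184 spots marked as outliers or non-uniform were left out. The spike-in transcripts gave slopes of 0.819 and 0.876 and correlations of 0.994 and 0.997, per the file headers. The number of arrays limits the precision of each value.

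Of 41174 gene probes, 23374 were matched to a gene by accession, 6733 by symbol and 2919 by synonym in the supplied table of mouse genes (GRCm38, used for names alone), and 8148 stayed unmatched. Probe positions are those of build mm8 in the files. 12 probes had no value on both arrays.

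The scanner-signal fit started from mean spot signals and local backgrounds. Background was corrected by normexp with offset 50, ratios were normalized by loess (span 0.3) within each array, and probes well above background in at least 1 channel on both arrays were kept. This left 8815 probes. The deposited-ratio fit used the deposited value table with no further scaling. In both fits limma 3.58.1 in R 4.3.3 tested each probe's mean log2 ratio against 0 (moderated test, 1 residual degree of freedom, two-sided), and p was adjusted by Benjamini-Hochberg over the tested probes. Genes were called at an adjusted p under 0.05. A gene with several probes took the probe with the highest mean intensity. Counts of genes beyond 2-fold (log2 of 1) on both arrays carry no test. Where all probes of a gene were dim in 1 channel, no fold is given. Every adjusted p in the text comes from limma.

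The gene lists were set before the data were examined, as were the scanner-signal fit, its thresholds and the rule for named genes; the deposited-ratio fit was planned as an alternative. They are 28 lists of textbook marker and pathway genes: splicing regulators, islet antigens, exocrine pancreas, fibroblastic stroma, endothelium, T cells, cytotoxic effectors, regulatory T cells, B cells, germinal centre, plasma cells, macrophages and monocytes, neutrophils, dendritic cells, erythroid cells and platelets, adipocytes, muscle, type I interferon, interferon-gamma with MHC genes, inflammatory cytokines, glucocorticoid targets, proliferation, glycolysis, oxidative phosphorylation, ER stress, immediate early and heat shock genes, circadian genes and ribosomal proteins. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The preset correlation was assumed and not measured. With an estimated correlation the test has 1 residual degree of freedom and could hardly reach the threshold. A high adjusted p from it therefore decides nothing about a list. Each list's median was also placed among 10000 random lists matched on intensity in 20 bins. The rule took the 12 genes with the largest positive and the 12 with the largest negative mean ratio among calls of the scanner-signal fit, the 3 members of each list with the smallest p, and Deaf1, Aire, Srsf10, Ptbp2, Ins1, Ins2, Foxp3 and Ifng whatever they showed. A few genes are not reported here. Any other gene named was chosen after its values were seen. These are further members of the lists, amylase Amy1, liver and Reg genes, and a few strongly changed genes.

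The code was tested on simulated data, 20 sets with 200 changed probes each. At a log2 change of 1 the scanner-signal fit recovered 94.2% and the deposited-ratio fit 87.4% of them. At a log2 change of 2 the recovered shares were 99.9% and 100%. False calls averaged 6.21% (range 1.10% to 16.4%) and 8.78% (range 1.19% to 24.6%). The simulated arrays were independent, had no intensity trend, and took their variances from each fit's own prior. The real arrays share the control pool and the dye orientation, so these rates check the code and do not give the false share of the real calls.

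The alternatives were median centring without loess, normexp with offset 10, no background correction, Agilent processed signals, no filter on dim probes, a filter on both channels, marked spots kept, the mean of a gene's probes, an eBayes trend with robust prior, other thresholds, treat at 1.5-fold, each array alone, and quantile normalization for the spread between arrays. A further loess on the deposited ratios, processed signals with the filter on both channels, single arrays of the deposited table, and the list tests on the deposited ratios were added after the data were seen. Control spots outside the value table were used only for the checks of background and of spike-ins.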

Results

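Gene expression in the pancreatic lymph node was measured in 2 hyperglycemic female NOD mice aged 16 weeks, each on 1 two-colour array against the same pool of 2 euglycemic mice. The pancreatic lymph node drains the pancreas and is where T cells first meet islet antigens. Blood glucose was above 500 mg/dl in the hyperglycemic mice and below 200 mg/dl in the pooled mice. A positive log2 ratio means a higher signal in the hyperglycemic mouse (Cy5) than in the pool (Cy3). The Cy5 channel was dim, with a median signal of 37.7 on array 1 and 38.2 on array 2 over a background of 35, and the Cy3 median was 234 and 81.2. Ratios are given from a fit of the deposited log2 ratios (4406 genes) and from a fit of the scanner signals (7297 genes), and each scanner-signal value is named as such. Gene values are mean log2 ratios ± SD over both mice (n = 2).

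The comparison asks which transcripts of the pancreatic lymph node differ between hyperglycemic and euglycemic mice. In the deposited ratios T cell genes and most interferon-inducible genes were lower in both hyperglycemic mice, and metallothioneins, Txnip, Herpud1, hemoglobins and most called digestive enzymes were higher. In the scanner-signal fit 0 of 17 T cell genes were called higher and 2 lower. Of 17 interferon-gamma and MHC genes there, 1 was called higher and 2 lower. Among 4405 genes tested in both fits, 190 were called higher in both and 51 lower in both. Independent lists of these sizes would share 95.7 higher and 9.39 lower genes. Both fits read the same 2 arrays, so a call in both is not independent support. Genes called in both included Herpud1, an endoplasmic reticulum protein of the unfolded protein response (mm8 chromosome 8, 97284346 to 97284405), at 2.52 ± 0.00, which is 5.75-fold higher, and 2.84 in the scanner-signal fit. Txnip, a glucose-induced inhibitor of thioredoxin (chromosome 3, 96646629 to 96646688), was 4.46-fold higher at 2.16 ± 0.32, and 3.0 in the scanner-signal fit.

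Of the 51 genes called lower in both fits, the 12 with the lowest scanner-signal ratios were Fabp1, the fatty acid carrier of liver and gut, at -3.34 ± 1.11 (10.1-fold lower, chromosome 6, 71134491 to 71134550), and the following, each with an SD of at most 0.65. BC048507 was at -2.47, Clec2d at -2.36, Traf1, a signalling adaptor of tumour necrosis factor receptors, at -2.35, and Lyl1, a hematopoietic transcription factor, at -2.30. The long noncoding RNA Neat1 was at -2.23, Dynll1 at -2.08, Lcp1 (leukocyte plastin) at -2.08, Nr4a1, an immediate early nuclear receptor, at -1.75, Ms4a6b at -1.65, Cfd (adipsin) at -1.63 and Ifi27 at -1.49. Their scanner-signal ratios ran from -1.83 for Fabp1 and -1.33 for Dynll1 to -0.95 for Ms4a6b, and all 12 were called lower in both fits.

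The genes raised most in the scanner-signal fit were members of the exocrine pancreas list, most of them digestive enzymes, with Pigt, which attaches membrane anchors, and the ribosomal protein Rplp1. Pigt (chromosome 2, 164199333 to 164199392) was at 6.96 in that fit and at 1.48 ± 0.39 in the deposited ratios, and Rplp1 at 5.32 and 0.91 ± 0.04. Trypsin Try5 (chromosome 6, 41241393 to 41241809) was at 6.46 and 1.51 ± 0.18. The same 2 values were 5.62 and 1.11 for Ctrb1, 5.42 and 0.66 for Zg16, 5.31 and 0.90 for Clps, 5.07 and 0.79 for Pnliprp1, 5.01 and 0.56 for Sycn, and 4.93 and 0.70 for Cpa1. Prss3 (5.35 and 0.49, adjusted p = 0.0889 in the deposited ratios) and Ctrc (5.29 and 0.45, adjusted p = 0.0591) were called in the scanner-signal fit alone. The scanner-signal SDs of the genes in this paragraph ran from 0.86 for Zg16 to 2.40 for Pigt. In that fit each of these genes had its higher ratio on array 1. Median centring of the scanner signals turned Zg16 to -0.024, Prss3 to -0.014, Ctrc to -0.24, Sycn to -0.10 and Cpa1 to -0.18. Across genes the median-centred ratios fell with intensity (Spearman's rho = -0.953). The sign of a bright or a dim gene with median centring thus follows largely from its brightness, and it decides no direction here or below.

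At an adjusted p under 0.05, 1103 genes were higher and 811 lower in the deposited ratios, and 385 higher and 51 lower in the scanner-signal fit. The share of calls that were higher was 57.6% in the deposited ratios, 88.3% in the scanner-signal fit, 44.7% with median centring, 54.0% with no background correction, 78.0% with offset 10 and 56.6% with an intensity trend in the variance. Of the higher calls of the scanner-signal fit, 322 lay in the decile of brightest genes, whose median ratio was 0.72. In the deposited ratios the decile of dimmest genes had the highest median, 0.68, with 283 higher and 0 lower calls. All gene probes there were well above background in both channels, and Cy5 was the dimmer channel. A dim gene could thus enter only with enough Cy5 signal, which favours high ratios in that decile. In processed signals the filter on both channels moved Spearman's rho of ratio with intensity from 0.136 to -0.247. 17 genes were called in opposite directions by the 2 fits. Agilent processed signals with the filter of the scanner-signal fit gave 0 calls in limma against 2789 genes at an unadjusted p under 0.05, and moved the median ratio of all genes from -0.04 to -0.17.

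**Figure D1:**
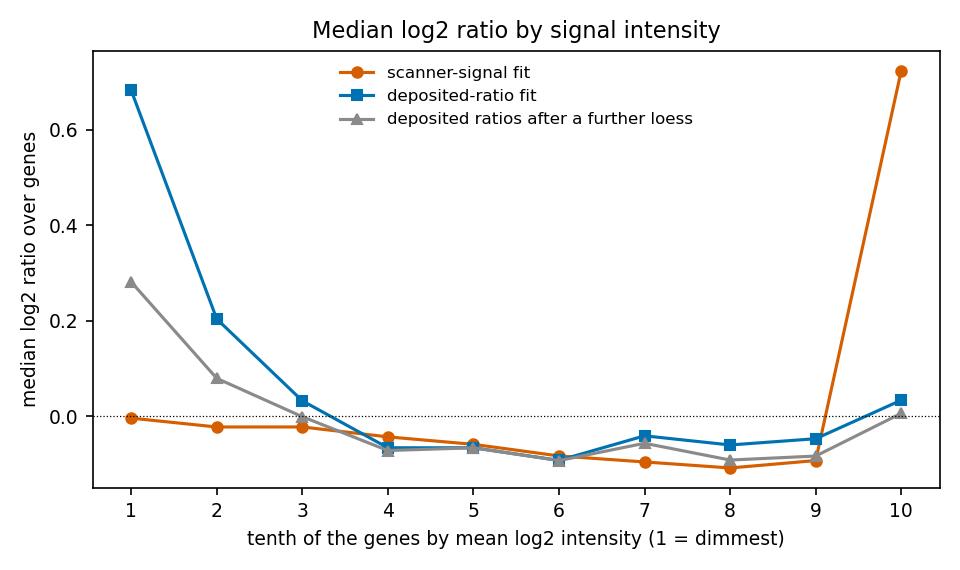
Median log2 ratio (y axis) of genes grouped in deciles of mean log2 intensity (x axis, 1 is the dimmest), 1 line each for the scanner-signal fit, the deposited ratios and the deposited ratios after a further loess. The brightest decile has a median of 0.72, 0.03 and 0.0062, and the dimmest decile 0.00, 0.68 and 0.28.

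**Figure D2:**
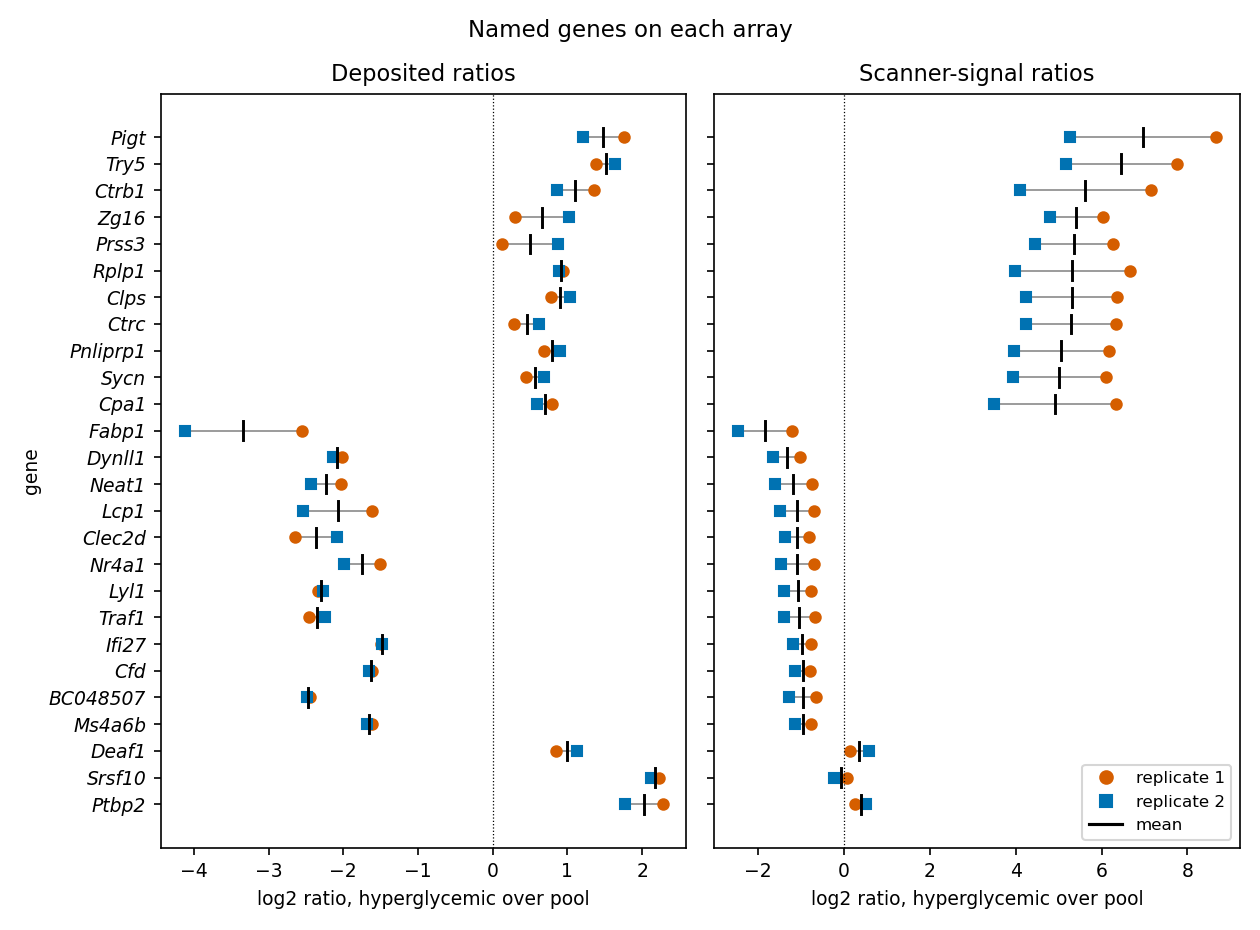
Log2 ratio of hyperglycemic mouse over control pool (x axis) for named genes (y axis), deposited ratios on the left and scanner-signal ratios on the right, with a circle for array 1, a square for array 2 and a bar for the mean. Try5 has means of 1.51 and 6.46, Fabp1 -3.34 and -1.83, and Srsf10 2.17 and, from another probe, -0.07.

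T cell genes were lower in both hyperglycemic mice. All 13 measured T cell genes fell in the deposited ratios, with a median of -0.91 (1.88-fold lower). Cd3g and Cd3d, chains of the T cell receptor complex, were at -1.86 ± 0.15 and -1.21 ± 0.09, the co-receptor Cd8a at -1.83 ± 0.22, the interleukin-7 receptor Il7r at -1.58 ± 0.12 and the T cell kinase Lck at -1.15 ± 0.56. The probe of Cd3g lies at chromosome 9, 44724628 to 44725212, and that of Cd8a at chromosome 6, 71306845 to 71306904. Adjusted over the list alone, 0 were higher and 13 lower, and camera gave an adjusted p of 3.9e-07, against an adjusted p of 0.635 with an estimated correlation. T cell genes of the scanner-signal fit had a median of -0.35 (camera adjusted p = 1.53e-06, adjusted p = 0.813 with an estimated correlation). 0 of 17 were higher there, 2 lower (Cd3d and Lck) and 15 not called, or 0 higher and 8 lower adjusted over the list alone. The list's median was below 0 under every scaling tried.

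Of the regulatory T cell genes, Tnfrsf18 fell at -1.99 ± 0.13 and Tnfrsf4 was at -0.35 ± 0.05 (adjusted p = 0.105), that is 0 higher and 1 lower of 2, also adjusted over the list alone. Regulatory T cell genes of the scanner-signal fit had a median of -0.26. 0 of 4 were called there, or 0 higher and 2 lower adjusted over the list alone. Both measured cytotoxic effector genes were lower, Nkg7 at -1.42 ± 0.56 and the chemokine Ccl5 at -0.73 ± 0.74, and adjusted over the list alone 0 were higher and 2 lower. Ccl5 was at 0.93 in the scanner-signal fit. Cytotoxic genes there had a median of -0.24 (camera adjusted p = 0.333, adjusted p = 0.813 with an estimated correlation), which was 0.15 with the filter on both channels. 0 of 6 were called there, or 1 higher and 2 lower adjusted over the list alone.

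Interferon-gamma and MHC genes were lower as well. Of 13 measured, 0 were higher, 11 lower and 2 not called, the same when adjusted over the list alone, with a median of -0.68 (1.61-fold lower). The interferon-induced GTPases Iigp1 (-1.61 ± 0.49) and Igtp (-1.57 ± 0.04), the immunoproteasome subunits Psmb8 (-1.53 ± 0.17) and Psmb9 (-0.89 ± 0.22) and the MHC class II chain H2-Aa (-0.89 ± 0.01) were among them. Camera gave an adjusted p of 4.57e-05, and the adjusted p was 0.635 with an estimated correlation. Interferon-gamma and MHC genes of the scanner-signal fit had a median of -0.19 (camera adjusted p = 0.0514, adjusted p = 0.813 with an estimated correlation). 1 of 17 was higher there and 2 lower, or 3 higher and 5 lower adjusted over the list alone. Under other processings of the scanner signals camera's adjusted p ran from 0.00136 to 0.0567 with the preset correlation. The median was below 0 under every scaling tried, but B2m, the light chain of MHC class I, was at 2.00 in the scanner-signal fit and at -0.60 ± 0.09 in the deposited ratios. Type I interferon genes of the scanner-signal fit had a median of -0.17 (0.01 with median centring; camera adjusted p = 0.0711, adjusted p = 0.813 with an estimated correlation). 0 of 5 were higher there and 1 lower, also adjusted over the list alone. Offset 10 and no filter put this list past the threshold as lower.

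Trypsin Try5, chymotrypsin Ctrb1, carboxypeptidases Cpa1 and Cpb1 and lipase Pnlip of the exocrine pancreas list were higher in the deposited ratios and amylase was lower, while with median centring of the scanner signals the list's median was -0.22. In the deposited ratios 12 of 28 were higher, 2 lower and 14 not called, the same when adjusted over the list alone, and the median was 0.61 (1.52-fold higher). Camera gave an adjusted p of 0.0383, which was 0.0504 after a further loess on intensity, and the adjusted p was 0.635 with an estimated correlation. The list's median was 4.46 in the scanner-signal fit, where random lists matched on intensity had a median of 1.46. 23 of 28 exocrine genes were higher in the scanner-signal fit and 0 lower, or 26 higher and 0 lower adjusted over the list alone. Camera there gave an adjusted p of 3.26e-30, against an adjusted p of 0.813 with an estimated correlation. The lower members in the deposited ratios were pancreatic amylase Amy2a5 at -2.15 ± 0.13 and elastase Cela1 at -0.73 ± 0.70, against 1.37 and 3.21 in the scanner-signal fit. Amy1, a near-identical amylase outside the list (chromosome 3, 113548096 to 113548155), was at -1.82 ± 0.02, against 1.94 in the scanner-signal fit. Another Amy1 probe was at -1.61, against 0.17 (adjusted p = 0.785), and another Amy2a5 probe, dim in Cy5, read -0.10 in the scanner-signal fit. Some enzymes varied between the mice, as Cpb1 at 0.89 ± 0.87 and Pnlip at 0.67 ± 0.50. The single measured islet antigen gene, Ins2, was at -0.25 ± 0.03 in the scanner-signal fit (adjusted p = 0.229) and 0.17 with median centring. It was dim in Cy5 on both arrays, and its other probe, also dim in Cy5, read -0.10 in the scanner-signal fit, so no fold is given. In processed signals the Ins2 probe read -3.25 on array 1 and -2.27 on array 2, and its other probe -1.38 and -2.31. The size of the Ins2 ratio thus depended on the processing. As a list of 1 gene, the islet antigens counted 0 higher and 1 lower adjusted over the list alone, where a single test needs no adjustment.

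Glucocorticoid target genes were higher in the deposited ratios and in the scanner-signal fit. With median centring, whose ratios fell with intensity, their median was -0.05. Of 11 measured, 7 were higher, 0 lower and 4 not called, the same when adjusted over the list alone, with a median of 0.79 (1.74-fold higher). They included the metal-binding metallothioneins Mt2 (1.59 ± 0.19, 3.01-fold) and Mt1 (1.42 ± 0.13, 2.67-fold), Errfi1, an inhibitor of epidermal growth factor receptors (1.32 ± 0.36), the clock gene Per1 (0.87 ± 0.04), the phosphatase Dusp1 (0.79 ± 0.42) and the glucocorticoid receptor co-chaperone Fkbp5 (0.67 ± 0.08). Tsc22d3, a classic target, was at 0.30 ± 0.18 (adjusted p = 0.160), and Sgk1 was at -0.03 ± 0.05. Camera gave an adjusted p of 0.0294, with an adjusted p of 0.635 with an estimated correlation. Glucocorticoid target genes of the scanner-signal fit had a median of 0.21 (camera adjusted p = 1.23e-04, adjusted p = 0.813 with an estimated correlation). 4 of 13 were higher there and 0 lower, also adjusted over the list alone. Against random lists matched on intensity the median stood at percentile 99.95 in the deposited ratios and 94.0 in the scanner-signal fit. With median centring Mt1 was at -0.12 and Errfi1 at -0.34.

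Circadian genes rose on both arrays, Tef at 1.32 ± 0.58, Per1 at 0.87 ± 0.04 and Dbp at 0.82 ± 0.15, 3 of 3 measured and also 3 adjusted over the list alone; the Dbp ratio was -0.22 with median centring. Circadian genes of the scanner-signal fit had a median of 0.14 (camera adjusted p = 0.0711, adjusted p = 0.813 with an estimated correlation). 0 of 6 were called there, also adjusted over the list alone. Median centring (median 0.73), offset 10, no background correction, processed signals and no filter put this list past the threshold, and over the alternatives camera's adjusted p ran from 0.00445 to 0.0704 with the preset correlation. Inflammatory genes of the nuclear factor kappa B response were higher for 3 of 4, Nfkbia at 0.95 ± 0.07, Vcam1 at 0.59 ± 0.16 and Tnfaip3 at 0.49 ± 0.20, with 0 lower. Median centring put Nfkbia at -0.83 and Vcam1 at -1.09. Adjusted over the list alone 3 were higher and 1 lower (Icam1, -0.42 ± 0.00). Inflammatory genes of the scanner-signal fit had a median of 0.22 that was -0.83 with median centring (camera adjusted p = 0.126, adjusted p = 0.813 with an estimated correlation). 1 of 5 was higher there and 0 lower, also adjusted over the list alone.

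Splicing regulators moved both ways. A probe of Srsf10, a splicing repressor related to the SR proteins, was 4.51-fold higher at 2.17 ± 0.07 (adjusted p = 4.73e-04; chromosome 4, 135130946 to 135131005). The other Srsf10 probes, outside the deposited table, read -0.17 and -0.35, 0.14 and -1.20, and 2.46 and -0.75 on arrays 1 and 2 in processed signals, so the value is that of 1 probe and not of the gene. Ptbp2, the neuronal polypyrimidine tract binding protein, was 4.07-fold higher at 2.03 ± 0.35 (adjusted p = 7.22e-04; chromosome 3, 119730986 to 119731045). Deaf1, a transcription factor that drives tissue antigen expression in lymph node stroma, was 1.99-fold higher at 0.99 ± 0.20 (adjusted p = 0.0035; chromosome 7, 141166259 to 141172439). The scanner-signal ratios were 0.36 for Deaf1 (adjusted p = 0.228), 0.40 for Ptbp2 (adjusted p = 0.132) and -0.07 ± 0.20 for Srsf10 (adjusted p = 0.767). That Srsf10 value comes from another, brighter probe, and the probe of the deposited ratio was at 0.60 in the scanner-signal fit (adjusted p = 0.137). A second Deaf1 probe read -0.80 and -1.38 in processed signals and was not well above background in Cy5, so the transcript forms behind these probes were not told apart.

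Of 35 splicing regulators in the deposited ratios 10 were higher, 4 lower and 21 not called, the same when adjusted over the list alone. Their median was 0.08 (camera adjusted p = 0.540, adjusted p = 0.635 with an estimated correlation). Srsf5 (1.37 ± 0.06), Ptbp3 (1.29 ± 0.01) and Hnrnpm (0.94 ± 0.13) were higher, and Elavl1 (-1.40 ± 0.24), Hnrnpa2b1 (-0.96 ± 0.01) and Tra2b (-0.49 ± 0.10) lower; Hnrnpm was at -0.69 with median centring. Splicing genes of the scanner-signal fit had a median of -0.04 that was -0.82 with median centring (camera adjusted p = 0.782, adjusted p = 0.943 with an estimated correlation). There Hnrnpm alone of 38 was higher, at 1.16, and 0 were lower, also adjusted over the list alone. Aire, the thymic regulator of tissue antigens, Ins1, Foxp3 and Ifng did not pass the filter on dim probes in either fit.

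B cell genes included lower and higher members. Of 7 measured, 4 were lower, among them Spib (-1.38 ± 0.15), Ms4a1 (CD20, -1.12 ± 0.06) and Fcmr (-1.05 ± 0.24). Pax5 (1.17 ± 0.75) was the 1 higher, and adjusted over the list alone 1 was higher and 5 lower. The median was -0.48, below 0 under every scaling tried (camera adjusted p = 0.0642, adjusted p = 0.635 with an estimated correlation). B cell genes of the scanner-signal fit had a median of -0.31 (camera adjusted p = 0.00587, adjusted p = 0.813 with an estimated correlation). There Ms4a1 and Fcmr were the 2 lower of 13, with 0 higher, or 0 higher and 6 lower adjusted over the list alone. Of 6 plasma cell genes, Ighg (-1.11 ± 0.07), Mzb1 (-0.83 ± 0.18), Jchain (-0.55 ± 0.04) and Ighm were lower and Fkbp11 (0.60 ± 0.43) and Derl3 (0.48 ± 0.24) higher, the same when adjusted over the list alone. Ighm was at -0.63 ± 0.09, against 1.18 in the scanner-signal fit. The plasma cell median was -0.59 (camera adjusted p = 0.184, adjusted p = 0.635 with an estimated correlation). Plasma cell genes of the scanner-signal fit had a median of 0.11, and -1.44 with median centring, while camera pointed down (adjusted p = 0.877, and adjusted p = 0.946 with an estimated correlation). 0 of 7 were higher there and 1 lower, or 1 higher and 3 lower adjusted over the list alone. Bcl6, the germinal centre repressor, was lower at -0.47 ± 0.15 and Pou2af1 was at -0.03 ± 0.05, 0 of 2 higher and 1 lower, also adjusted over the list alone. Germinal centre genes of the scanner-signal fit had a median of -0.07. 0 of 4 were called there, also adjusted over the list alone.

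Among myeloid genes the scavenger receptor Marco (0.60 ± 0.24), Adgre1 (0.54 ± 0.39) and C1qc (0.51 ± 0.02) were higher and C1qa (-0.55 ± 0.13) lower, which makes 3 and 1 of 8 macrophage and monocyte genes. Adjusted over the list alone 4 were higher and 2 lower. The median was 0.34, and -0.17 with median centring of the scanner signals, where Marco was at -0.81 (camera adjusted p = 0.540, adjusted p = 0.635 with an estimated correlation). Macrophage and monocyte genes of the scanner-signal fit had a median of 0.04 (camera adjusted p = 0.115, adjusted p = 0.813 with an estimated correlation). 3 of 15 were higher there and 0 lower, also adjusted over the list alone. Lysozyme Lyz1 was among them at 0.68, against -0.46 ± 0.18 in the deposited ratios (adjusted p = 0.0507). The neutrophil alarmin S100a9, the only neutrophil gene in the deposited ratios, was higher at 1.46 ± 0.46, also adjusted over the list alone, and at -0.071 with median centring. Neutrophil genes of the scanner-signal fit had a median of 0.26, and 1 of 3 was higher and 0 lower, also adjusted over the list alone. Cd83, a marker of mature dendritic cells, was lower at -1.34 ± 0.15 and Irf8 was at 0.26 ± 0.04 (adjusted p = 0.206), 0 of 2 higher and 1 lower, also adjusted over the list alone. Dendritic cell genes of the scanner-signal fit had a median of -0.09 (camera adjusted p = 0.482, adjusted p = 0.813 with an estimated correlation). 0 of 5 were higher there and 1 lower, or 1 higher and 1 lower adjusted over the list alone.

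Red cell genes were higher in the deposited ratios, with a median of 0.94 that was -0.01 with median centring of the scanner signals. The hemoglobin genes Hba-a1 (1.23 ± 0.20) and Hbb-bt (1.17 ± 0.10), the heme synthesis enzyme Alas2 (1.10 ± 0.35) and the band 3 anion exchanger Slc4a1 (0.78 ± 0.14) were the 4 higher of 6 erythroid and platelet genes, with 0 lower, also adjusted over the list alone. Camera gave an adjusted p of 0.0642 for the list, and the adjusted p was 0.635 with an estimated correlation. Hba-a1 was at -0.21 with median centring. Erythroid and platelet genes of the scanner-signal fit had a median of 0.25 (camera adjusted p = 0.00978, adjusted p = 0.813 with an estimated correlation). 2 of 6 were higher there and 0 lower, also adjusted over the list alone. The median stood at percentile 99.8 of lists matched on intensity in the deposited ratios and 92.9 in the scanner-signal fit.

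Adipocyte genes were lower for 4 of 8, the lipid droplet protein Cidec (-1.91 ± 0.45), Cfd (-1.63 ± 0.03), the desaturase Scd1 (-1.38 ± 0.53) and Plin4 (-1.22 ± 0.12), and higher for 1, the lipase Pnpla2 (0.78 ± 0.37). Adjusted over the list alone 2 were higher and 5 lower, and the median was -0.82, below 0 under every scaling tried (camera adjusted p = 0.0642, adjusted p = 0.635 with an estimated correlation). Adipocyte genes of the scanner-signal fit had a median of -0.24 (camera adjusted p = 0.0464, adjusted p = 0.813 with an estimated correlation). 0 of 11 were higher there and 1 (Cfd) lower, or 2 higher and 5 lower adjusted over the list alone. Endothelial genes Kdr, the receptor of vascular endothelial growth factor (1.62 ± 0.34), Cldn5 (1.38 ± 0.25), Lyve1 (0.71 ± 0.32) and Robo4 (0.45 ± 0.05) were the 4 higher of 8, with 0 lower, or 5 higher and 1 lower adjusted over the list alone. Glycam1, a marker of high endothelial venules, was at -0.42 ± 0.04 (adjusted p = 0.0621), against 1.36 in the scanner-signal fit. The endothelial median was 0.55 (camera adjusted p = 0.0695, adjusted p = 0.635 with an estimated correlation), at percentile 87.0 of random lists matched on intensity, whose median was 0.27. Endothelial genes of the scanner-signal fit had a median of 0.17 (camera adjusted p = 0.0145, adjusted p = 0.813 with an estimated correlation). 1 of 9 was higher there and 0 lower, or 2 higher and 0 lower adjusted over the list alone.

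Stromal genes split, with Lum (1.20 ± 0.07), Ltbr (1.11 ± 0.48), decorin Dcn (1.00 ± 0.49) and the B cell chemokine Cxcl13 (0.71 ± 0.21) higher. Ccl19, the T zone chemokine (-1.04 ± 0.00), and collagen Col3a1 (-0.76 ± 0.20) were lower. These were 4 and 2 of 10, or 4 higher and 3 lower adjusted over the list alone. Ccl19 was at 0.96 in the scanner-signal fit, and with median centring Dcn was at -0.67 and Cxcl13 at -1.10. The median was 0.02 in the deposited ratios (camera adjusted p = 0.975, adjusted p = 0.983 with an estimated correlation). Stromal genes of the scanner-signal fit had a median of 0.15, and -0.63 with median centring (camera adjusted p = 0.130, adjusted p = 0.813 with an estimated correlation). 1 of 14 was higher there and 0 lower, or 2 higher and 0 lower adjusted over the list alone. The single muscle gene, Tnni2, was at -0.04 ± 0.05 in the scanner-signal fit (adjusted p = 0.838), not called either when adjusted over the list alone, and at 0.090 with median centring.

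Ribosomal protein genes differed between the fits. In the deposited ratios 4 of 36 were higher and 5 lower, the same when adjusted over the list alone, and the median was 0.01 while camera pointed down (adjusted p = 0.540, and adjusted p = 0.635 with an estimated correlation). Ribosomal protein genes of the scanner-signal fit had a median of 2.60 (6.04-fold) that was -1.32 with median centring (camera adjusted p = 3e-25, adjusted p = 0.813 with an estimated correlation). 30 of 36 were higher there and 0 lower, or 32 higher and 1 lower adjusted over the list alone. Rpl38 was at 0.77 ± 0.22 and Rpl15 at -0.63 ± 0.41, against 4.46 and 1.56 in the scanner-signal fit. Of 24 oxidative phosphorylation genes 2 were higher, Atp5a1 (1.04 ± 0.29) and Cox7a2 (0.58 ± 0.24), and cytochrome c (Cycs, -0.86 ± 0.17) was lower, or 1 higher and 1 lower adjusted over the list alone; Atp5a1 was at -0.81 with median centring. The median was 0.18 (camera adjusted p = 0.486, adjusted p = 0.635 with an estimated correlation). Oxidative phosphorylation genes of the scanner-signal fit had a median of 0.18 that was -1.31 with median centring (camera adjusted p = 2.50e-04, adjusted p = 0.813 with an estimated correlation). 7 of 26 were higher there and 0 lower, or 9 higher and 1 lower adjusted over the list alone, and the median stood at percentile 85.4 of lists matched on intensity. Such lists had a median of 1.47 for the ribosomal genes of the scanner-signal fit.

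Of 12 glycolysis genes Tpi1 (-1.24 ± 0.20), Pgam1 (-0.88 ± 0.17), Ldha (-0.79 ± 0.15) and Hk1 (-0.52 ± 0.27) were lower and Txnip, which limits glucose uptake, was higher, or 1 higher and 5 lower adjusted over the list alone. Their median was -0.23 (camera adjusted p = 0.184, adjusted p = 0.635 with an estimated correlation). Glycolysis genes of the scanner-signal fit had a median of -0.09 (camera adjusted p = 0.782, adjusted p = 0.946 with an estimated correlation). 1 of 14 was higher there and 0 lower, or 3 higher and 2 lower adjusted over the list alone. Herpud1 was the 1 higher of 11 ER stress genes, and Edem1 (-1.18 ± 0.38) and calreticulin Calr (-1.01 ± 0.27) were lower, also adjusted over the list alone. The chaperone Hspa5 was at 0.47 ± 0.31 (adjusted p = 0.0615) and at -1.32 with median centring. The ER stress median was 0.00 (camera adjusted p = 0.618, adjusted p = 0.813 with an estimated correlation). ER stress genes of the scanner-signal fit had a median of -0.12 (camera adjusted p = 0.756, adjusted p = 0.946 with an estimated correlation). 1 of 16 was higher there and 0 lower, or 2 higher and 0 lower adjusted over the list alone.

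Of 14 immediate early and heat shock genes, Nr4a1, Dnajb1 (-1.19 ± 0.29), Hspa8 (-0.90 ± 0.28), Zfp36 (-0.90 ± 0.32) and Myc (-0.77 ± 0.06) were lower and the Krüppel-like factors Klf4 (1.77 ± 0.02), Klf2 (0.97 ± 0.19) and Klf6 (0.63 ± 0.26) higher, the same when adjusted over the list alone. The median was -0.33 (camera adjusted p = 0.184, adjusted p = 0.635 with an estimated correlation), and Klf2 was at -0.77 with median centring. Immediate early and heat shock genes of the scanner-signal fit had a median of -0.18 (camera adjusted p = 0.194, adjusted p = 0.817 with an estimated correlation). 1 of 18 was higher there and 2 lower, or 3 higher and 2 lower adjusted over the list alone. Of 9 proliferation genes the replication clamp Pcna (-0.67 ± 0.10) and Mki67 (-0.54 ± 0.01) were lower and Birc5 (0.96 ± 0.68, and -0.40 with median centring) higher, also adjusted over the list alone. The proliferation median was -0.37 (camera adjusted p = 0.330, adjusted p = 0.635 with an estimated correlation). Proliferation genes of the scanner-signal fit had a median of -0.13 (camera adjusted p = 0.0960, adjusted p = 0.813 with an estimated correlation). 0 of 17 were called there, also adjusted over the list alone. Lower lists past the threshold in camera with median centring included plasma cell, splicing and immediate early genes, and with no filter they included immediate early, proliferation, cytotoxic and regulatory T cell genes.

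**Figure D3:**
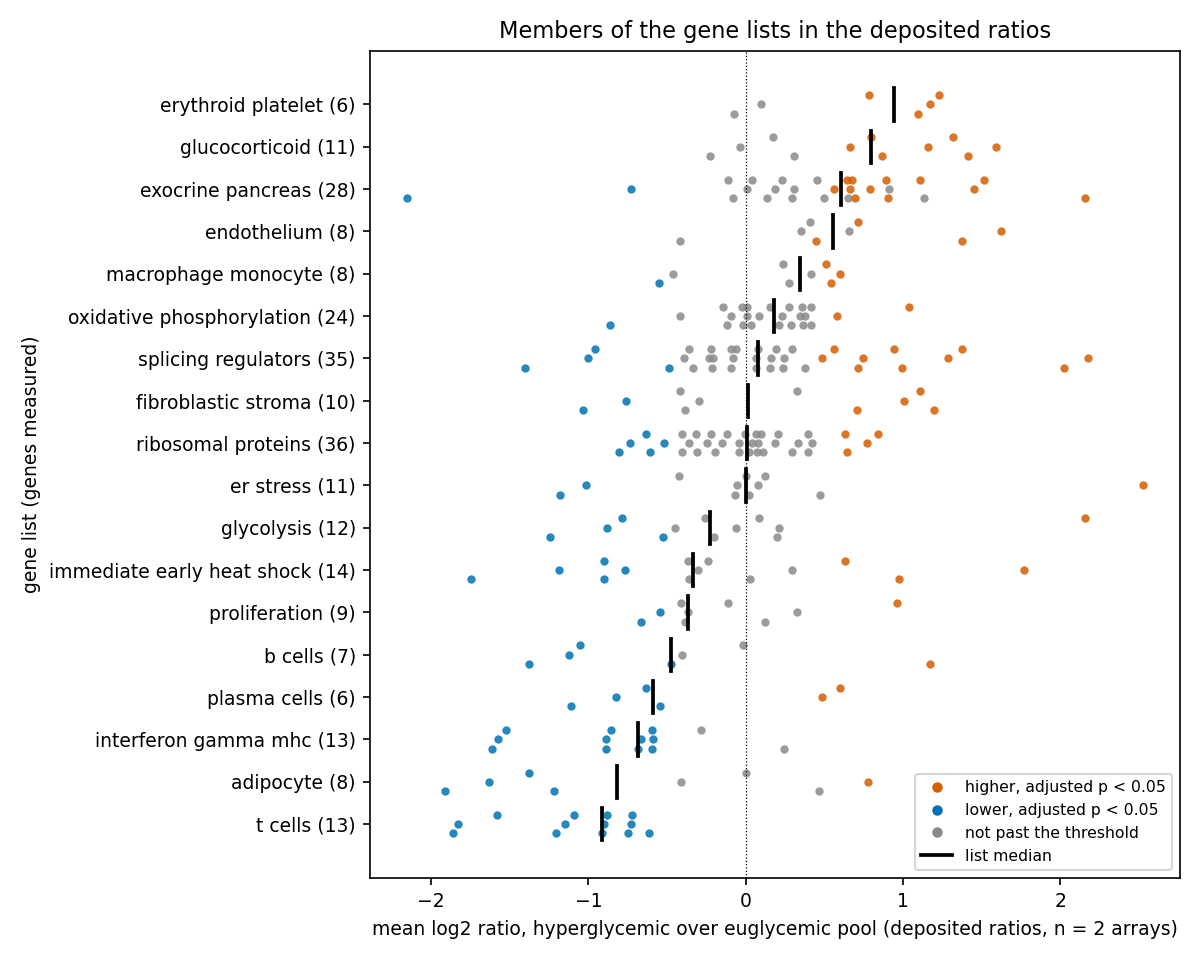
Mean log2 ratio over n = 2 arrays in the deposited ratios (x axis) of each member (points) of each gene list with at least 5 measured genes (y axis), coloured by its call, with a bar at the list's median. T cell genes have a median of -0.91 and are all lower, and exocrine genes have a median of 0.61, which was -0.22 with median centring of the scanner signals.

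At a threshold of 2-fold on both arrays, with no test, 238 genes were higher and 124 lower in the deposited ratios, and 230 and 2 in the scanner-signal fit. Array 1 alone had 431 genes higher and 197 lower beyond 2-fold in the deposited ratios, and array 2 alone 343 and 223. Across genes, which are not independent replicates, the ratios of the 2 arrays correlated with r = 0.829 and Spearman's rho = 0.824 in the deposited ratios, where 81.7% of genes had the same sign on both. The values were r = 0.842, rho = 0.731 and 75.8% in the scanner-signal fit. These correlations include the control pool that both arrays share. Over 8815 probes the difference between the arrays had an SD of 0.27 in Cy3, where both arrays held the pool, and of 0.33 in Cy5, where they held different mice. The log2 ratios of the 2 arrays correlated at 0.840 over these probes. In processed signals of probes well above background in both channels the SD was 0.17 in Cy3 and 0.44 in Cy5.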

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

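The tests of the spike-in transcripts were chosen after their results were seen.

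A signal appeared in spots outside the comparisons: the 153 negative control spots of array 1 had a median Cy3 signal of 51.0 over a local background of 31, a ratio of 1.64. The ratio was 1.45 on array 2 (45.6 over 31.5), and in Cy5 the same spots lay at 36.0 and 36.6 over a background of 35.

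Bright probes had high ratios in the scanner-signal fit, where the decile of brightest genes had a median of 0.72 and held 322 of the 385 higher calls. A candidate explanation is an intensity trend that this normalization left in place. 3 spike-in transcripts whose mean ratios lay within 0.04 of each other in the processed signals lay 1.33 apart in the scanner-signal fit (2.15 on array 1 and 0.61 on array 2). Over all 10 spike-ins the scanner-signal ratio minus the processed ratio rose with intensity (Spearman's rho = 0.952 across spike-ins, permutation p = 1.4e-04, two-sided, 100000 permutations), as a trend in one of the 2 would give. Per the file headers, observed spike-in ratios correlated with the expected ones at 0.994 on array 1 and 0.997 on array 2. For the spike-ins these values argue against a trend of that size in the processed ratios. In the deposited ratios the brightest decile had a median of 0.034 (0.0062 after a further loess), with 99 genes higher and 78 lower, and a true rise of bright transcripts in the hyperglycemic mice was not tested beyond that.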

How the results depend on the processing

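A further loess on the deposited ratios, processed signals with the filter on both channels, single arrays of the deposited table and list tests on the deposited ratios were chosen after the data were seen; the other alternatives were planned. The reference is the scanner-signal fit, with 385 genes higher and 51 lower, 230 and 2 beyond 2-fold, and 6 lists higher and 3 lower. Offset 10, marked spots kept, the mean of a gene's probes, the intensity trend and an adjusted p under 0.10 left the higher count within 1.5 times (305, 367, 351, 557 and 498). Among 104 named genes, no background correction and offset 10 turned 0 directions. Marked spots kept and no filter on dim probes also turned 0, which says little about stability. The filter acts after normalization and leaves a probe's ratio as it was, and few spots were marked. The low Cy5 signal over background limits the scanner-signal fit, in which 1706 genes were dim in Cy5 on both arrays. The deposited ratios cover 5072 gene probes, all well above background in both channels, and the rule that chose them is not stated. Except where a threshold or the set of probes was changed, the cause was not tested.

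Genes called higher numbered 2168 with median centring, 1082 with no background correction, 0 with processed signals (2789 genes at an unadjusted p under 0.05 in limma), 23 with no filter, 163 with the filter on both channels, 1103 in the deposited table, 1000 after a further loess and 1106 in processed signals with the filter on both channels. They numbered 850 at an unadjusted p under 0.05 and 155 with treat at 1.5-fold. Genes called lower numbered 2683 with median centring, 86 with offset 10, 923 with no background correction, 0 with processed signals, 0 with no filter (2697 genes at an unadjusted p under 0.05 in limma, both directions), 1 with the filter on both channels, 811 in the deposited table, 427 with the intensity trend, 943 after a further loess and 814 in processed signals with the filter on both channels. They numbered 135 at an adjusted p under 0.10, 690 at an unadjusted p under 0.05 and 0 with treat.

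Genes beyond 2-fold higher on both arrays numbered 421 with processed signals and 353 beyond 1.5-fold, 270 to 365 without a replicate, and 431 in array 1 alone of the deposited table. Those lower numbered 1067 with median centring, 15 with offset 10, 38 with no background correction, 697 with processed signals, 124 in the deposited table and in processed signals with the filter on both channels, 133 after a further loess, 22 beyond 1.5-fold, 4 to 49 without a replicate, and 197 and 223 in arrays 1 and 2 alone of the deposited table.

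Lists past the threshold numbered 1 higher and 9 lower with median centring, 5 lower with offset 10, 9 lower with no filter, 1 lower with the filter on both channels, 2 higher in the deposited table and in processed signals with the filter on both channels, and 1 higher after a further loess. With an estimated correlation 0 were higher and 0 lower, in the scanner-signal fit and in the deposited table alike. That test has 1 residual degree of freedom and could hardly reach the threshold, so its counts decide nothing. Fry gave 1 higher and 0 lower in the scanner-signal fit, and 0 and 0 in the deposited table. The spread between arrays (SD) in Cy3 was 0.20 with the filter on both channels and 0.17 in processed signals so filtered, and that in Cy5 was 0.29 with quantile normalization and 0.44 in processed signals so filtered. The correlation of the arrays' log2 ratios was 0.735 with quantile normalization.

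Named genes turned direction as follows. Median-centred ratios fell with intensity across genes (Spearman's rho = -0.953), so a turn with that setting decides no direction. In the deposited table, and in processed signals with either filter, Ccl19 was at -1.04, Glycam1 at -0.42, Ccl5 at -0.73, Ighm at -0.63, Lyz1 at -0.46, B2m at -0.60, Gpi1 at -0.063, Rpl15 at -0.63 and Rpl10 at -0.25, and after a further loess at -1.04, -0.42, -0.74, -0.64, -0.45, -0.63, -0.048, -0.67 and -0.32. Srsf10 was at 2.17 in the deposited table and 2.12 after a further loess, 0.60 with the filter on both channels, 0.27 as the mean of its probes, and -0.21 to 0.072 without a replicate. With median centring 44 genes turned: Zg16 -0.024, Prss3 -0.014, Ctrc -0.24, Sycn -0.10, Cpa1 -0.18, Hnrnpm -0.69, Hnrnpf -1.47, Ins2 0.17, Reg1 -0.50, Cpb1 -0.11, Cxcl13 -1.10, Dcn -0.67, Ccl19 -2.44, Glycam1 -1.93, Ccl5 -2.25, Neil1 0.65, Ighm -2.17, Lyz2 -0.93, Marco -0.81, Lyz1 -2.14, S100a9 -0.071, Mmp9 1.15. The others were Irf8 -1.49, Ccr9 0.39, Hba-a1 -0.21, Tnni2 0.090, Cxcl10 0.011, B2m -1.79, Nfkbia -0.83, Vcam1 -1.09, Mt1 -0.12, Errfi1 -0.34, Birc5 -0.40, Gpi1 -1.78, Atp5a1 -0.81, Atp5b -1.53, Ndufa2 -1.47, Hspa5 -1.32, Klf2 -0.77, Dbp -0.22, Rpl15 -2.01, Rpl38 -0.19, Rpl10 -1.51 and Srsf10 0.23.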

Other observations

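The tests of explanations in this part were chosen after their results were seen, and so were the genes named outside the T cell list.

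Among the genes with high ratios in both mice, 5 are given here because their ratios were high. Pdpk1, the kinase that activates Akt, was 8.21-fold higher in the deposited ratios (log2 3.04 ± 0.31, SD, n = 2) and at 2.17 in the scanner-signal fit, and glutamine synthetase Glul was at 2.30 ± 0.28 and 2.45. Sesn1, an inhibitor of mTORC1 signalling, was at 2.02 ± 0.16 and 2.29, and the cold-inducible RNA-binding protein Cirbp at 1.77 ± 0.14 and 1.75, all 4 called in both fits. Klf15, a glucocorticoid-induced transcription factor, was at 2.07 ± 0.24 in the deposited ratios and at 0.70 in the scanner-signal fit (adjusted p = 0.0943). The interferon-induced GTPase Tgtp1 was lower at -2.53 ± 0.02, and at -0.82 in the scanner-signal fit (adjusted p = 0.0591).

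Reg and liver genes were among those that differed most between the 2 hyperglycemic mice in the deposited ratios, beside genes of neither kind such as Cwc15 (1.03 on array 1 and 3.55 on array 2) and Zfp979 (-0.42 and 2.03). The difference between the mice was not tested. The Reg genes, which encode secreted lectins of injured pancreas and gut, were higher on array 2: Reg3a was at -0.79 on array 1 and 3.06 on array 2, Reg3b at 0.35 and 3.97, Reg2 at -0.45 and 2.26, Reg3d at -0.23 and 2.06, and Reg1 at -0.04 and 1.34. In the scanner-signal fit Reg1 was at 4.08 and 3.77 and Reg2 at 3.60 and 4.52, so both were high on both arrays. Transcripts of the liver were lower on array 2: albumin Alb was at -1.23 on array 1 and -2.90 on array 2, Ahsg at -1.08 and -3.21, Rbp4 at -0.53 and -3.39, and Apoc1 at -0.15 and -2.22. Their scanner-signal ratios on arrays 1 and 2 were 0.72 and -2.01 for Alb, -0.21 and -2.12 for Ahsg, and -0.24 and -1.92 for Rbp4. Apoc1 was at 1.32 and -1.42 there, so Alb and Apoc1 were above 0 on array 1 in that fit. Reg3a and Reg3b had the largest differences between the arrays, 3.85 and 3.61.

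Amylase transcripts were lower while most called digestive enzymes were higher in the deposited ratios. More pancreas carried over into the hyperglycemic samples would raise each acinar transcript and lower none. The mean of Amy1 and Amy2a5 was -1.98, or -4.47 SD from the median of 27 other acinar genes (0.65, SD 0.59). Carry-over alone would leave these low amylase values of the deposited ratios unexplained. The pair was picked for being low, so the distance cannot decide whether pancreas was carried over. In the scanner-signal fit Amy1 was at 1.94 and Amy2a5 at 1.37, below that list's median of 4.46, and another probe of each read 0.17 (Amy1, adjusted p = 0.785) and -0.10 (Amy2a5, dim in Cy5). A bias of bright probes stays open: Amy1 stood at percentile 2 of the 50 genes nearest in intensity, but the pair was picked for being low, and near-identical amylase genes count as 1 observation. A lower level of amylase relative to other enzymes in the pancreas of hyperglycemic mice, or a dye effect of these probes, may account for it, and neither was tested.

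T cell genes were lower in the deposited ratios, with a median of -0.91 over 13 genes. A bias tied to signal intensity is argued against, because the median stood at percentile 0 of 10000 random lists matched on intensity. A lower share of lymphocytes alone would raise the markers of every other cell type alike. The medians of 5 other cell types (stroma, endothelium, macrophages, erythroid cells, adipocytes) spread over 1.76 log2 units (permutation p = 0.00177 for a range as wide, one-sided, 100000 permutations). Erythroid cells (0.94) and adipocytes (-0.82) set that range, each with a camera adjusted p of 0.0642. Stroma was at 0.02, macrophages at 0.34 and endothelium at 0.55. In the scanner-signal fit the 5 medians ran only from -0.24 to 0.25. Shuffling treats genes expressed together as independent, so the test cannot decide whether a change in share is the whole of it. With 0 dye-swapped arrays a dye effect of single genes cannot be told apart from the difference between the groups. A lower expression of T cell genes, or a lower share of T cells, alone or together with other shifts in cell types, may be behind the pattern. These were not told apart.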
